A study of Mus musculus with 30 samples.

How the data were processed

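Gene expression was measured by RNA sequencing in 30 libraries from the thymus of newborn mice of strain B6.SJL and mixed sex. Per the labels, mice were given aflibercept (called Trap here) or human Fc protein (control) on postnatal day 1, and thymi were taken on postnatal day 3. Aflibercept is a fusion of parts of the VEGF receptors 1 and 2 that binds VEGF-A in solution. Thymi were digested and depleted of CD45-positive cells on magnetic beads, and 5 stromal populations were sorted by flow cytometry. These were CD140a-positive mesenchyme, CD146-positive mesenchyme, cortical thymic epithelial cells (cTEC, high in Ly51), medullary thymic epithelial cells (mTEC, low in or lacking Ly51) and CD31-positive endothelium. Each population had 2 control and 4 Trap libraries. The labels number the replicates but do not say how many animals a library holds or whether libraries of different populations come from the same animals, so the p-values measure only the spread between these libraries, part of which may be technical.

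Per the labels' protocols, total RNA was extracted with a column kit, cDNA was made and amplified with the Ovation RNA-Seq System V2, libraries were built with the KAPA LTP kit and pairs of reads were sequenced on a HiSeq3000. Per the submitters' processing notes, bcl2fastq version 2.17, STAR and DESeq2 were used with the mouse builds GRCm38 and mm10. The version of STAR and DESeq2, the role of each tool, the gene annotation and the counting program are not given in the sources used here. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the fragments of a library) for 18847 genes of the protein-coding type, rounded to 2 decimals, with an Ensembl identifier and a symbol for each gene. Of these identifiers, 18836 were found in the GENCODE M21 annotation of GRCm38, from which the coordinates below are taken. A total of 27 symbols had been turned into dates by a spreadsheet, and all 27 were restored through their Ensembl identifiers. Mitochondrial genes, genes that do not code for protein and any read counts were not analysed here.

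FPKM values carry no depth of their own. The steps between low values were searched for the worth of 1 read, but in only 7 of the 30 libraries did the score exceed that of shuffled values, and the best score was 0.379 where 1 means that each value is a whole multiple. The depth behind each value is therefore unknown, no counting interval can be given, and how precise a value is can be read only from the spread between libraries. The FPKM values deposited by the authors summed to between 184608 and 241993 per library, and 10298 to 13661 genes reached 1 FPKM. RNA was amplified before library construction, so a low value near 0 can reflect loss during amplification. An exact 0 means here only that the gene is listed at 0.

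All tests were run in R 4.3.3 with limma 3.58.1. Values were transformed as log2(FPKM + 1), genes reaching 1 FPKM in at least 2 libraries were kept (16425), and a mean was fitted for each of the 10 groups over all 30 libraries, with empirical Bayes moderation and a trend in the variance. Every fold change is a difference on that scale, which understates changes of genes at low levels. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were Trap against control in each population, the Trap change in endothelium against the mean Trap change of the other 4 populations, each population against the mean of the other 4, cTEC against mTEC, and CD140a-positive against CD146-positive mesenchyme. With 2 control libraries in each population, the fit borrowed each gene's spread from all groups. The tests, the samples in each, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

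Genes named for a Trap contrast were the 10 higher and the 10 lower genes with the largest change among those that passed, whose 4 Trap libraries lay on 1 side of both controls and whose higher group mean was at least 5 FPKM, together with up to 4 members of smallest p from each list described. Where fewer than 5 genes passed in a direction, all were named, and where none passed, the 5 of smallest p in each direction were named under the same conditions. For cTEC against mTEC, for the mesenchymal populations and for the difference of Trap changes, the 8 largest changes in each direction were named at a level of at least 5 FPKM. The VEGF list and the sorting markers Pecam1, Epcam, Enpep, Mcam, Pdgfra and Ptprc were always included, and symbols that are only identifiers and sex-linked genes were left out of the rankings. Population markers were taken from the list of each population, with examples. Members of lists that are not described are not all printed, and 1 gene of a described list is not reported here.

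A total of 31 gene lists were written: VEGF ligands and receptors, pan-endothelial, tip cell, arterial, venous, capillary and lymphatic endothelium, Notch pathway, basement membrane, cTEC, mTEC, tissue-restricted antigens, tuft-like epithelium, pan-epithelial, thymopoietic factors, MHC class II, pericyte and smooth muscle, fibroblast, hypoxia, cell cycle, p53 targets, immediate early stress genes, interferon response, cholesterol synthesis, thymocyte, erythroid, myeloid, neural and glial, mesothelial and parathyroid, Y-linked genes and mitochondrial genes. Of their 398 symbols, 18 had no matching entry in the table used here, among them the whole mitochondrial list, so 30 lists were tested. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over 150 tests (30 lists in 5 populations). For the difference of Trap changes, adjustment was over the 30 lists of that contrast alone. Camera with an estimated correlation and fry, which asks only whether a list's genes move on balance in 1 direction, were alternatives.

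The fits were first tested on simulated data drawn from each population's own means and spreads. With no change simulated, the pooled fit called a median of 205.5 genes in endothelium, 111 in mTEC, 20 in CD146-positive mesenchyme, 4.5 in CD140a-positive mesenchyme and 1 in cTEC over 20 simulations, because endothelial and medullary libraries varied more than the spread they borrowed. A fit on only the 6 libraries of a population called at most 2 genes in any such simulation of the populations, but recovered only 7.6% of endothelial genes changed by 1 on the log2 scale, against 72.2% for the pooled fit. The pooled fit made a median of 415 calls there with 200 genes changed, so many of its calls were false. A cell-cycle list lowered by 1 on the log2 scale in endothelium was found in 5 of 5 simulations, and 1 unchanged list was called in all of them together. Each gene was simulated independently of the others, so these runs do not test how camera treats lists whose genes vary together. After these results were seen, a fit with 1 weight per population (limma's arrayWeights) and fry on only the 6 libraries of a population were added. The weights were 1.23 for CD140a-positive mesenchyme, 1.08 for CD146-positive mesenchyme, 1.66 for cTEC, 0.794 for mTEC and 0.573 for endothelium.

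Other alternatives were a pseudocount of 0.1, no filter and a filter at 5 FPKM, upper quartile scaling, rescaling to the same sum (TPM), quantile normalization, weights per library, only the 6 libraries of a population, control libraries only, the replicate number as a block, and each library left out in turn. Restriction to genes expressed in the population, the Y-linked level as a covariate, extra list tests and leaving out mTEC Trap replicates 1 and 2 together were added after the data had been seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.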

Results

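Stromal cells of the neonatal mouse thymus were profiled to ask how withdrawal of vascular endothelial growth factor (VEGF) alters each cell type that surrounds developing T cells. The 30 RNA sequencing libraries covered 5 sorted populations, each with 2 libraries from mice given control Fc protein and 4 from mice given Trap, a soluble VEGF decoy receptor, 2 days before collection. The values were the authors' FPKM, which summed to 184608 to 241993 per library, with an unknown number of reads behind them. Between 10298 (endothelium, Trap replicate 2) and 13661 (mTEC, control replicate 2) genes reached 1 FPKM in a library. The mTEC libraries held the most such genes, 13518 ± 203 in controls (SD, n = 2) and 13173 ± 406 with Trap (SD, n = 4), and the endothelial libraries 11234 ± 99.7 and 10777 ± 420. Pearson correlations of log2 values across genes were 0.881 to 0.980 within a population and 0.603 to 0.868 between populations, and no pair of libraries was identical.

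The transcripts of the proteins used for sorting lay in the populations they were sorted for. Pdgfra, which encodes CD140a, stood at 121 ± 9.92 FPKM in CD140a-positive mesenchyme (SD, n = 6, as for all population levels here). Pecam1, which encodes CD31, stood at 321 ± 14.9 FPKM in endothelium, and Epcam at 306 ± 17.4 FPKM in cTEC and 472 ± 66.5 FPKM in mTEC. Enpep, the gene of Ly51, was at 22.7 ± 1.82 FPKM in cTEC and 2.00 FPKM in mTEC. Mcam, the gene of CD146, was at 131 ± 18.0 FPKM in CD146-positive mesenchyme and 110 ± 18.7 FPKM in endothelium. Ptprc, the gene of the leukocyte antigen CD45 used for depletion, was at 5.03 ± 1.68 FPKM in cTEC and at most 0.76 FPKM on average elsewhere. In GRCm38, Pecam1 lies on the minus strand of chromosome 11 at 106654217 to 106750628, Epcam on the plus strand of chromosome 17 at 87635979 to 87651129, and Pdgfra on the plus strand of chromosome 5 at 75152292 to 75198215.

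**Figure D1:**
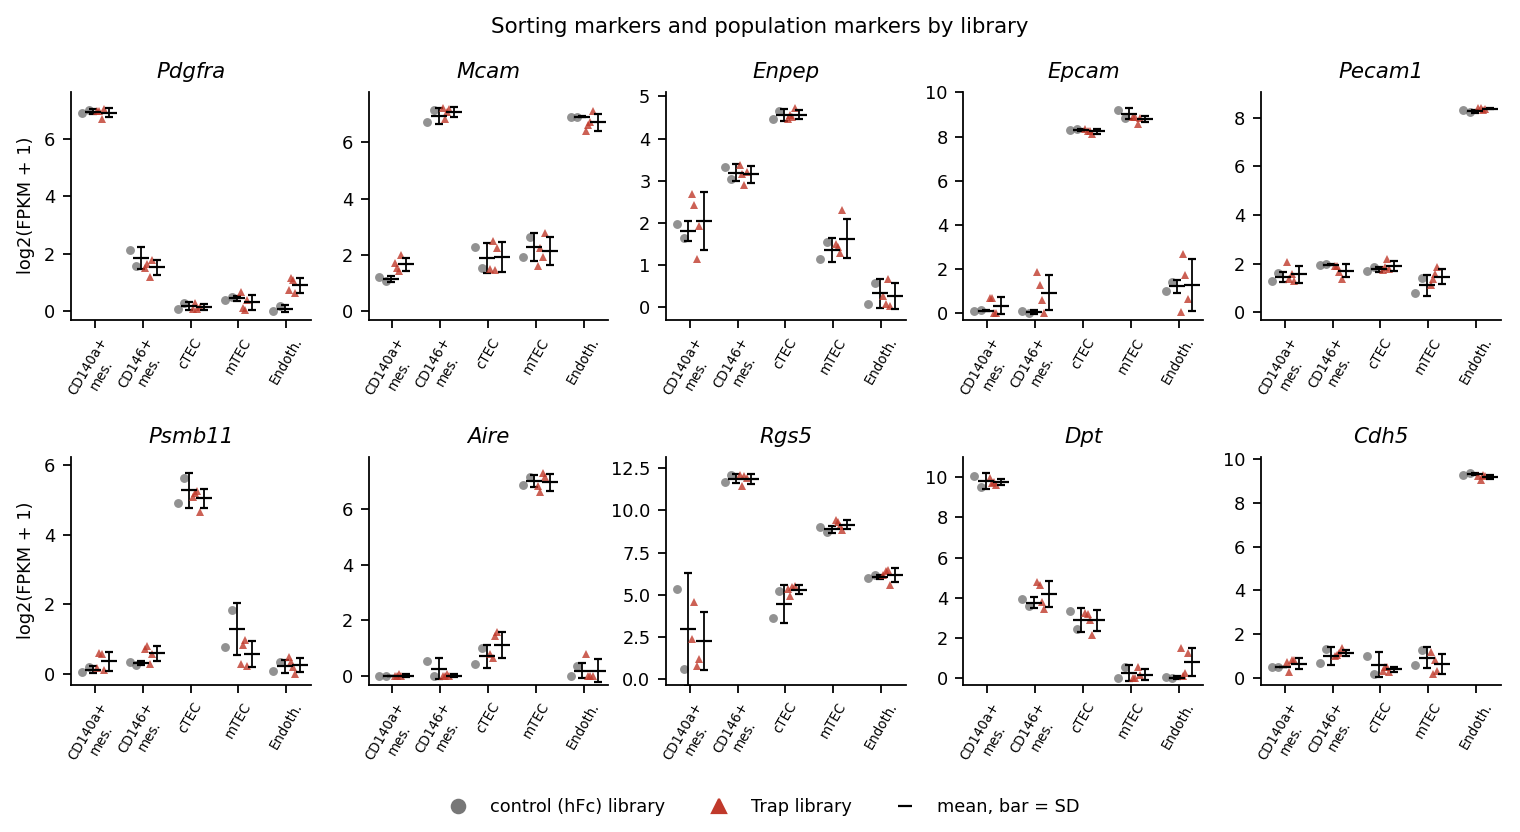
Levels of 10 marker genes, as log2(FPKM + 1), in each of the 30 libraries by population (circles, 2 control libraries; triangles, 4 Trap libraries; black dash and bar, mean and SD). Pecam1 and Cdh5 stand apart in endothelium, Epcam in cTEC and mTEC, Psmb11 in cTEC, Aire in mTEC, Pdgfra and Dpt in CD140a-positive mesenchyme, and Rgs5 is highest in CD146-positive mesenchyme.

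Each population was compared with the mean of the other 4, and each was higher in its own marker list. In CD140a-positive mesenchyme, all 17 fibroblast markers were higher, with a median log2 difference of 4.99. The fibrillar collagens Col1a1 (7.78 ± 0.27, SE) and Col3a1 (7.76 ± 0.13), the small leucine-rich proteoglycans Dcn (6.88 ± 0.20) and Lum (7.41 ± 0.19), and the matrix protein gene Dpt (7.89 ± 0.21) were among them, and Pi16 and Dpp4, which mark adventitial fibroblasts, were higher by 4.99 and 4.22. In limma 2805 genes were higher and 5422 lower, and the median over all genes was -0.19. Quantile normalization gave 3498 and 4144 and moved that median by 0.11.

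In CD146-positive mesenchyme, all 16 pericyte and smooth muscle markers were higher, with a median log2 difference of 4.11. Rgs5, a regulator of G-protein signalling found in pericytes, reached 3781 ± 630 FPKM, and Acta2 and Myh11, which encode smooth muscle actin and myosin, reached 753 ± 276 and 449 ± 28.8 FPKM. Notch3 and Pdgfrb, receptors of mural cells, were higher by 5.21 ± 0.21 and 4.80 ± 0.11 (log2, SE). In limma 2984 genes were higher and 4105 lower, and rescaling to TPM gave 3858 and 3458.

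In cTEC, all 16 markers of its list were higher, with a median log2 difference of 4.57. Psmb11, the cortex-specific subunit of the thymoproteasome (4.69 ± 0.16, SE), Prss16, a thymus-specific serine protease (7.18 ± 0.34), Foxn1, the transcription factor needed for thymic epithelium (4.60 ± 0.32), and Il7, a cytokine for early thymocytes (4.55 ± 0.15), were among them. Of 10 pan-epithelial genes 8 were higher in cTEC, the tight junction gene Cldn7 was lower by -0.96 ± 0.21, and Krt19 (-0.16 ± 0.23) did not pass and lay above 0 after rescaling to TPM (0.56). Of 14 thymocyte genes 13 were higher in cTEC, at a median of 5.72 FPKM, which stands beside each gene group given for cTEC. In limma 3488 genes were higher and 4029 lower.

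In mTEC, all 18 markers of its list and all 10 pan-epithelial genes were higher, with median log2 differences of 4.98 and 4.46. Aire (6.66 ± 0.16, SE) and Fezf2 (6.46 ± 0.15), which drive expression of tissue-restricted antigens, the basal keratins Krt5 (6.63 ± 0.26) and Krt14 (6.25 ± 0.15), and the costimulatory gene Cd80 (5.14 ± 0.24) were among them, and 12 of 13 tissue-restricted antigens were higher, with a median of 3.38. In limma 6304 genes were higher and 2868 lower. The split depended on scaling, with 5042 and 3936 after upper quartile scaling and 4268 and 5753 after quantile normalization, which moved the median of all genes by -0.16 and -0.33.

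In endothelium, all 16 pan-endothelial genes were higher, with a median log2 difference of 5.61, and so were all 12 venous genes (3.04), 10 of 12 arterial genes (1.91) and 13 of 16 tip cell genes (1.58). Cdh5, the adhesion molecule of endothelial junctions, stood at 600 ± 39.8 FPKM, and the VEGF receptors Kdr and Flt1 at 114 ± 22.9 and 126 ± 12.2 FPKM, with log2 differences of 6.60 ± 0.12 and 5.48 ± 0.12 (SE). In limma 2900 genes were higher and 5661 lower, and quantile normalization gave 3643 and 4368 and moved the median of all genes by 0.13.

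Between the epithelial populations, cTEC held more transcript of Prss16, Psmb11 and Ly75 and mTEC more of Pth, Aire and Lyz1. Prss16 was higher in cTEC (318 ± 47.4 against 7.48 ± 3.16 FPKM), as were Psmb11 (34.6 ± 8.21 against 0.90 ± 0.871) and Ly75, an endocytic receptor (136 ± 12.3 against 11.2 ± 3.47). The chemokine gene Cxcl12 (log2 difference 3.75 ± 0.20, SE), the cadherin gene Cdh4 (3.63 ± 0.21), Neurl2 (4.64 ± 0.36), Prr32 (4.14 ± 0.22) and Rag1, the recombinase of lymphocytes (4.00 ± 0.28), made up the rest of the 8 largest. Higher in mTEC were the parathyroid hormone gene Pth (log2 difference -8.73 ± 0.70, SE), Aire (-6.07 ± 0.20), the lysozymes Lyz1 and Lyz2 (-7.02 ± 0.22 and -6.88 ± 0.28), Lypd8, the taste transducin gene Gnat3, the trypsin inhibitor gene Spink1, and Bcl2a1b. Lyz1 and Lyz2 are near-identical copies, as Bcl2a1b is of its neighbours, so their values are uncertain. In limma 2116 genes were higher in cTEC and 4652 in mTEC. Upper quartile scaling gave 2967 and 3815 and quantile normalization 4003 and 3080, moving the median of all genes by 0.13 and 0.28.

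The mesenchymal populations differed as fibroblasts differ from mural cells. Ly6a, a surface antigen of fibroblasts and progenitors, stood at 461 ± 78.1 FPKM in CD140a-positive against 3.19 ± 2.10 FPKM in CD146-positive mesenchyme. The scavenger receptor Scara5 (log2 difference 6.37 ± 0.17, SE), the angiotensin receptor Agtr2 (6.36 ± 0.27), the microfibril gene Mfap5 (6.29 ± 0.28), Clec3b, Akr1c18, the imprinted gene Zim1 and the enkephalin gene Penk (6.01 ± 0.43) were also higher there. Rgs5 (-9.26 ± 0.58), Myh11 (-8.04 ± 0.19), Map3k7cl (-6.78 ± 0.48), Acta2 (-6.15 ± 0.38), Fhl5, the guanylate cyclase gene Gucy1a3, Olfr558 and Mcam (-5.61 ± 0.21) were higher in CD146-positive mesenchyme. In limma 2220 genes were higher in CD140a-positive and 2900 in CD146-positive mesenchyme, and upper quartile scaling gave 2525 and 2458.

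In endothelium, the cell type that carries the VEGF receptors, 11 of 23 cell-cycle genes fell with Trap. The list passed in camera (adjusted p = 3.14e-20) and fry (adjusted p = 7.75e-04), not with an estimated correlation (adjusted p = 0.0713 with an estimated correlation) and not in fry on the 6 endothelial libraries alone (adjusted p = 0.186). All 23 measured genes of the cell-cycle list lay lower, with a median log2 change of -1.06. The 11 fell when adjusted over all genes, and 19 when adjusted over the list alone. Kif11, a motor protein of the mitotic spindle, fell from 11.8 ± 2.04 FPKM (SD, n = 2) to 1.75 ± 0.486 FPKM (SD, n = 4), a log2 change of -2.23 ± 0.25 (SE; limma adjusted p = 3.18e-05). The ribonucleotide reductase gene Rrm2 (-1.98 ± 0.36), the replication clamp gene Pcna (-0.91 ± 0.15) and the helicase subunit gene Mcm4 (-1.22 ± 0.23) also fell, with limma adjusted p = 0.00479, 0.00223 and 0.00517. Endothelial control replicate 2 held the most influence, and without it the list's adjusted p was 1.84e-12. Kif11 lies on the plus strand of chromosome 19 at 37376403 to 37421859, Rrm2 on the plus strand of chromosome 12 at 24708241 to 24714146, and Pcna on the minus strand of chromosome 2 at 132249162 to 132253314.

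Of 16 genes of endothelial tip cells, the leading cells of vascular sprouts, 2 fell with Trap, Kcne3 and Esm1. The tip list passed in camera (adjusted p = 0.00215) and fry (adjusted p = 8.79e-05), and was lost with an estimated correlation (adjusted p = 0.0642 with an estimated correlation) and without control replicate 2 (adjusted p = 0.0523). The median log2 change of the 16 was -0.76, with 11 below 0 and 9 lower adjusted over the list alone. Kcne3, a potassium channel subunit, fell from 5.83 ± 1.15 to 0.782 ± 0.702 FPKM (log2 change -2.02 ± 0.25, SE; limma adjusted p = 1.17e-04). Esm1, a secreted proteoglycan induced by VEGF, fell by 2.88 on the log2 scale (SE 0.72; limma adjusted p = 0.0352), but its Trap values were 0.67 to 2.71 FPKM in 3 libraries and 38.5 FPKM in Trap replicate 2, against 33.7 and 43.5 FPKM in controls. Transcripts of thymic epithelium were also high in that library, named after their values were seen. Of the cTEC list, Tbata was at 26.0 FPKM against 0.07 to 4.37 in the other 5 endothelial libraries, Prss16 at 11.6 against 0 to 1.59, and Foxn1 at 11.04 against 0.04 to 0.11, but Psmb11 at 0.27 against 0.01 to 0.41. Of the mTEC list, the keratin gene Krt5 was at 7.43 against 0.06 to 0.68 and Ccl21a at 202 against 16.4 to 85.5. Esm1 was at 0.17 to 0.44 FPKM in cTEC and 0 to 2.30 FPKM in mTEC. Leaving out either endothelial control or Trap replicate 1, 3 or 4 ended the Esm1 call. Igfbp3 (-1.06 ± 0.29, limma adjusted p = 0.0625) and Nid2 (-0.70 ± 0.22, limma adjusted p = 0.102) did not pass. Kcne3 lies on the plus strand of chromosome 7 at 100176502 to 100184869 and Esm1 on the plus strand of chromosome 13 at 113209659 to 113218098.

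**Figure D2:**
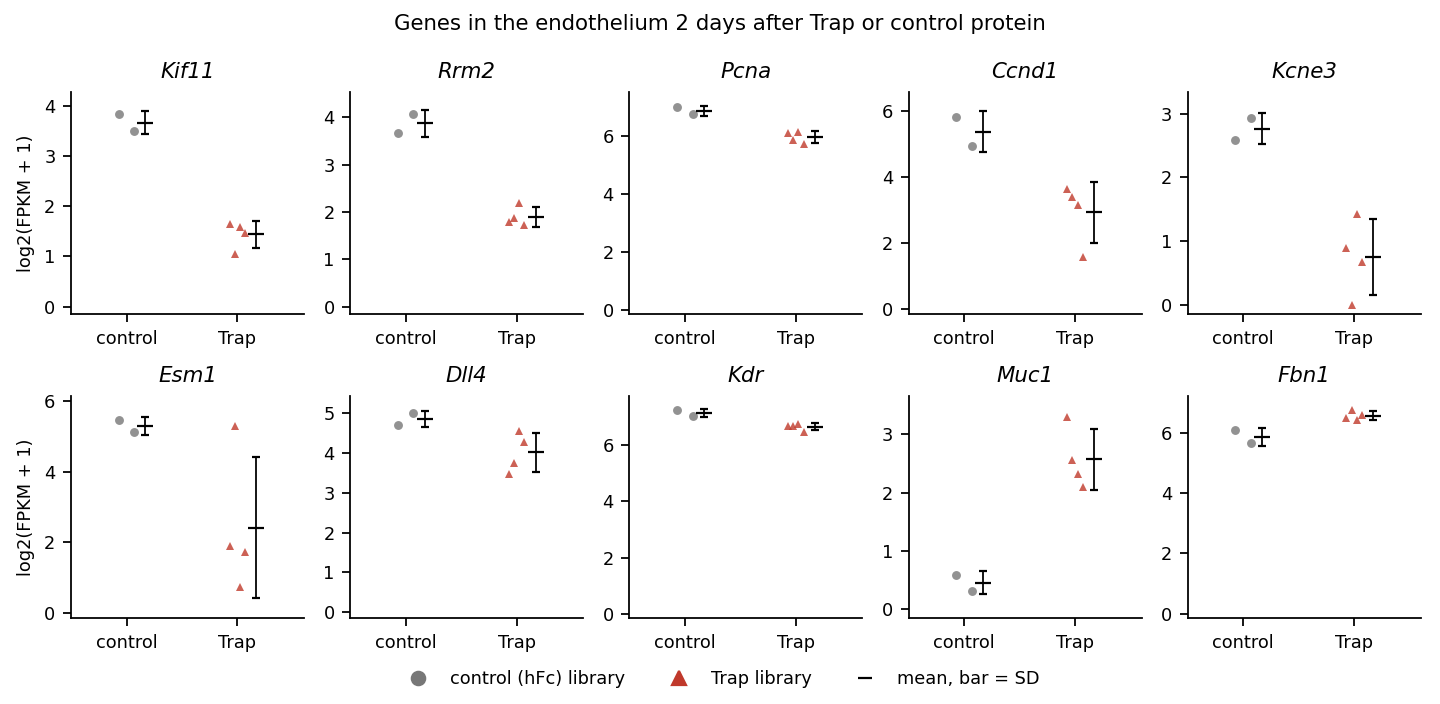
Levels of 10 genes in the 6 endothelial libraries, as log2(FPKM + 1), for control (circles, 2 libraries) and Trap (triangles, 4 libraries), with mean and SD beside the points. Kif11, Rrm2, Pcna, Ccnd1 and Kcne3 lie lower in all 4 Trap libraries, 1 Trap library keeps Esm1 at the control level, Dll4 and Kdr lie lower without passing the test, and Muc1 and Fbn1 lie higher.

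Over all genes, limma called 53 higher and 233 lower with Trap in endothelium. The lower genes of largest change were the histone genes Hist1h2bb (-3.34 ± 0.71, log2 change and SE) and Hist1h2bj (-3.03 ± 0.54), the secreted protein gene Scgb3a1, the replication factor genes Gins1 (-2.51 ± 0.41) and Rpa3 (-2.36 ± 0.43), Morn3, the cyclin D1 gene Ccnd1 (42.4 ± 18.0 to 7.68 ± 4.06 FPKM), Murc, Ifit1bl1 and Lrrc3b. Histone genes of that cluster are near-identical copies, so their values are uncertain. The higher genes of largest change were the mucin gene Muc1 (0.38 ± 0.184 to 5.26 ± 2.50 FPKM), Yif1b (1.83 ± 0.35), Ap4m1, the ghrelin gene Ghrl, the forkhead gene Foxp4 (2.06 to 7.57 FPKM), Klhl21, Fam107a, Rab11fip5, Ankrd46 and Prorsd1. The venule addressin gene Madcam1 (-1.10 ± 0.26), the capillary gene Gpihbp1 (-0.76 ± 0.19) and the T cell kinase gene Lck (-1.44 ± 0.37) fell, while Vwf (0.79 ± 0.26) and Tll1 (0.96 ± 0.30), of the venous list, did not pass. Of the 32 called genes named for endothelium, 23 lost the call without control replicate 1, 14 without control replicate 2, 9 without Trap replicate 4, 8 without Trap replicate 2 and at most 6 without any other library. The count was 89 without control replicate 1, 468 without control replicate 2 and 263 without Trap replicate 2, the library with the fewest genes at 1 FPKM and a mean log2 level of the cTEC list of 3.14 against 1.55 to 2.15 in the other 5. Simulations with no change gave a median of 205.5 calls (170 to 254 over 20 simulations) by the same limma fit, so a large part of the 286 calls is the number that the spread between endothelial libraries gives alone. The fit on the 6 endothelial libraries called 0 (869 at an unadjusted p under 0.05, against 2452 in the main test). The fit with 1 weight per population gave 0 higher and 13 lower, Kif11 and Kcne3 among them, against a median of 33.5 in simulations with no change. Rescaling to TPM gave 76 higher and 189 lower.

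Of 17 fibroblast genes 2 rose in endothelium with Trap, and 5 adjusted over the list alone, with 14 above 0 and a median log2 change of 0.36. The list's camera adjusted p was 2.51e-04, lost with an estimated correlation (adjusted p = 0.188 with an estimated correlation) and without control replicate 2 (adjusted p = 0.110). Fbn1, the fibrillin gene, rose from 58.0 ± 12.3 to 94.3 ± 9.73 FPKM (0.70 ± 0.17; limma adjusted p = 0.0287) and Pi16 from 0.175 ± 0.163 to 1.93 ± 1.37 FPKM (limma adjusted p = 0.0439). Pdgfra (0.06 to 0.895 FPKM; 0.82 ± 0.23) and Col6a3 (0.57 ± 0.19) did not pass. In CD140a-positive mesenchyme, Pi16 was at 23.6 to 71.8 FPKM and Pdgfra at 103 to 131 FPKM. Fbn1, Pi16, Pdgfra and Col6a3 lay above both endothelial controls in every Trap library and were each highest in Trap replicate 2. Among 16 interferon genes 15 lay lower (median -0.35) and Ifit2 fell (-1.19 ± 0.31; limma adjusted p = 0.0472), with 2 lower adjusted over the list alone. That list's camera adjusted p was 0.0457, lost with an estimated correlation (adjusted p = 0.942 with an estimated correlation) and without control replicate 1 (adjusted p = 0.921). Irf7 (-1.12 ± 0.34) and Usp18 (-0.69 ± 0.31) did not pass.

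The Trap change in endothelium was then set against the mean Trap change of the other 4 populations. List p-values were adjusted here over 30 lists, not over 150 tests, so they are not on the same footing as those above. Tip genes differed by a median of -0.78 on the log2 scale (camera adjusted p = 3.02e-05; adjusted p = 0.00202 with an estimated correlation). Cell-cycle genes differed by -0.93 (camera adjusted p = 4.86e-14; adjusted p = 0.0670 with an estimated correlation), fibroblast genes by 0.40 (3.02e-05; adjusted p = 0.0561 with an estimated correlation) and basement membrane genes by -0.30 (0.0337; adjusted p = 0.531 with an estimated correlation). In limma 8 single genes differed upwards and 38 downwards. Muc1 (2.24 ± 0.44, SE), Foxp4 (1.51 ± 0.30), Mthfsl, Rab11fip5, the transcription factor gene Nfil3, the phospholipase gene Plcb4 and the cytokine receptor gene Il6st (0.71 ± 0.15) differed upwards, and Hist1h2bj (-3.18 ± 0.61), Cdc42ep5, Gins1 (-2.47 ± 0.46), Ccnd1 (-2.28 ± 0.48), Olfr1394, the lactalbumin gene Lalba (-2.13 ± 0.30), Rrm2 (-1.94 ± 0.40) and Catip downwards. Quantile normalization gave 8 and 20. Of the 15 named, 11 lost the call without endothelial control replicate 1, 8 without CD140a control replicate 1 and at most 6 without any other library. The count was 223 without endothelial control replicate 2, 78 without Trap replicate 1 and 98 without Trap replicate 3. Simulations with no change gave a median of 98 (52 to 147) by the same fit, so the 46 genes do not exceed what the spread between libraries gives.

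**Figure D3:**
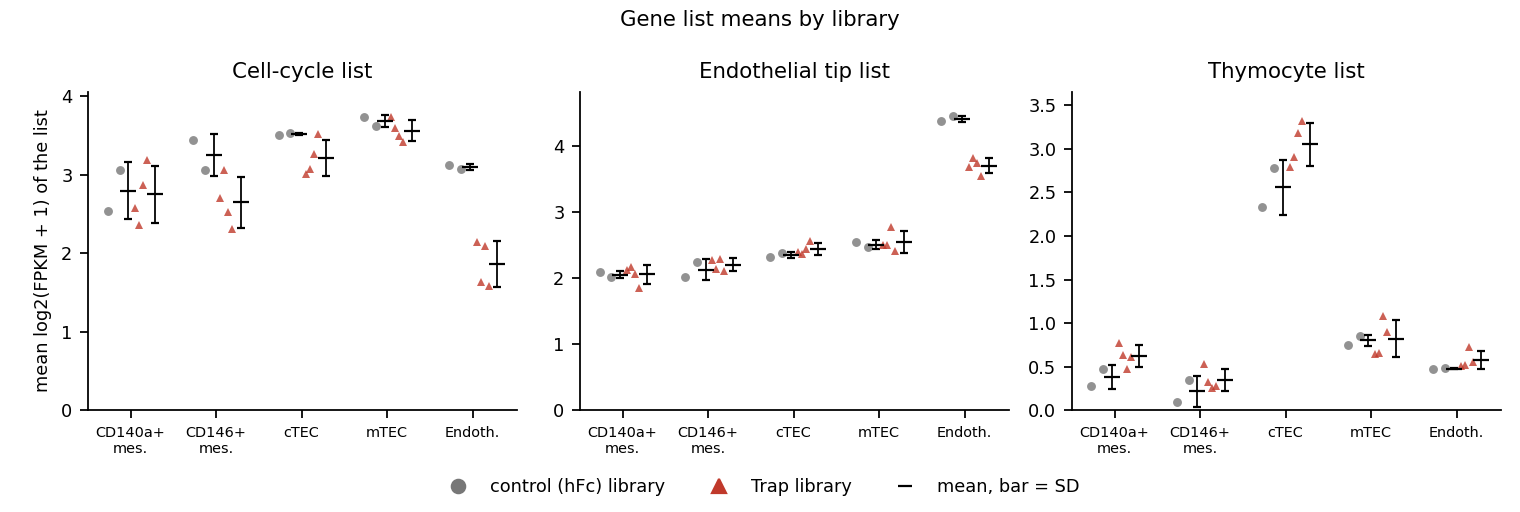
Mean log2(FPKM + 1) of the cell-cycle, endothelial tip and thymocyte lists in each of the 30 libraries by population (circles, control; triangles, Trap; dash and bar, mean and SD). In endothelium all 4 Trap libraries lie below both controls for the cell-cycle and tip lists, and in cTEC all 4 lie above both controls for the thymocyte list.

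In mTEC, Chat, a marker of tuft-like epithelial cells, and the homeobox gene Rhox2a were called lower with Trap, among no more calls than simulations with no change gave. Outside mTEC, Chat was at 0.02 FPKM or less and Rhox2a at 0, so their SE is borrowed in part from populations in which they are silent. The 7 genes of the tuft list had a median log2 change of -0.67. The list mean was 3.78 and 3.38 in controls and 2.54 to 3.39 with Trap, so the groups overlapped. The list's camera adjusted p was 0.00736, lost with an estimated correlation (adjusted p = 0.353 with an estimated correlation), without control replicate 1 (adjusted p = 0.217) or Trap replicate 1 (adjusted p = 0.104), and without Trap replicates 1 and 2 together (adjusted p = 0.148). Those 2 libraries stood apart, with 12815 and 12828 genes at 1 FPKM against 13374 to 13661 in the other 4 mTEC libraries. Their mean log2 levels were 2.48 and 2.59 against 2.98 to 3.27 for the myeloid list and 3.95 and 3.58 against 4.32 to 4.69 for tissue-restricted antigens. Chat, which encodes choline acetyltransferase, fell from 3.63 ± 1.00 FPKM (SD, n = 2) to 1.47 ± 0.845 FPKM (SD, n = 4; log2 change -0.96 ± 0.20, SE; limma adjusted p = 0.0219), while Avil (-0.97 ± 0.28), the taste channel gene Trpm5 (-0.72 ± 0.27) and Gnat3 (-0.55 ± 0.28) did not pass over all genes. Adjusted over the list alone 3 genes were lower. Over all genes limma called 4 higher and 53 lower. Spata2 rose (8.13 ± 0.636 to 15.4 ± 1.36 FPKM), as did the actin regulator gene Coro1a, the homeobox gene Nkx2-4 and Odam. The rule names these 3 since fewer than 5 genes rose, though they were added after their values were seen. Rhox2a (7.94 ± 3.32 to 0.605 ± 0.968 FPKM; -2.59 ± 0.27), the kallikrein genes Klk1b9 (-1.98 ± 0.29) and Klk1b22 (-1.18 ± 0.19), Lmntd2, the keratin gene Krt13, the bitter taste receptor gene Tas2r117 (-1.50 ± 0.24), Pcp4, the carboxylesterase gene Ces1d, Hsd17b6 and the germ-cell gene Dppa3 fell. The Rhox2 and kallikrein genes are families of near-identical copies, so their values are uncertain. Of the 15 called genes named here, 12 lost the call without control replicate 1, 5 without control replicate 2 and at most 3 without any other library. The count was 30 without control replicate 1, 149 without control replicate 2, and 88, 93, 103 and 103 without Trap replicates 1 to 4. It was 138 (72 higher, 66 lower) without Trap replicates 1 and 2 together, where Spata2, Pcp4 and Ces1d lost the call and Nkx2-4 was not tested. The same fit called a median of 111 genes (80 to 145) in simulations with no change, so the 57 calls do not exceed that number. The fit on the 6 mTEC libraries called 0 (795 at an unadjusted p under 0.05), and 1 weight per population called 46, against 53 with no change simulated.

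In CD146-positive mesenchyme, 22 of 23 cell-cycle genes lay lower with Trap, with a median log2 change of -0.61, but 1 fell over all genes and 2 adjusted over the list alone. The list's camera adjusted p was 1.33e-12, lost with an estimated correlation (adjusted p = 0.260 with an estimated correlation) and in fry (adjusted p = 0.180). The gene that fell was Mcm3, a subunit of the replicative helicase, which fell from 10.4 to 3.58 FPKM on average over 2 and 4 libraries (log2 change -1.35 ± 0.23, SE; limma adjusted p = 0.0240), while Kif11 (-0.94 ± 0.25), Pcna (-0.41 ± 0.15) and Mcm4 (-0.61 ± 0.23) did not pass. The only other calls in limma were the unnamed locus RP23-149C6.7, which fell by 2.39 on the log2 scale, and the olfactory receptor gene Olfr560, which rose by 1.19, both chosen for naming with all calls. Hbb-bs, a haemoglobin gene, was at 6.41 ± 6.37 FPKM in controls and 0.0525 ± 0.105 with Trap without passing (limma adjusted p = 0.366). The count of 3 became 19 without control replicate 1, 8 without control replicate 2, 5 without Trap replicate 2 or without endothelial Trap replicate 2, and 6 without Trap replicate 4, Mcm3 and Olfr560 losing the call without either control. Simulations with no change gave a median of 20, and the fit on the 6 libraries called 0 (731 at an unadjusted p under 0.05).

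In cTEC, thymocyte genes lay higher with Trap and cell-cycle genes lower, both as lists only. Both lists were lost with an estimated correlation (adjusted p = 0.0713 with an estimated correlation for thymocyte and adjusted p = 0.706 with an estimated correlation for cell-cycle genes). Of 14 thymocyte genes 12 lay higher, with a median log2 change of 0.51, and none passed in limma over all genes or adjusted over the list alone (374 genes at an unadjusted p under 0.05 in the contrast, and 0 calls in the fit on 6 libraries, with 741). Dntt, the polymerase that adds nucleotides during receptor rearrangement, was at 5.17 ± 0.481 and 11.1 ± 1.64 FPKM, and Cd8b1, Cd4, Themis and Ptprc had log2 changes of 1.16 ± 0.60, 0.77 ± 0.41, 0.49 ± 0.23 and 0.43 ± 0.23 (SE). The list's camera adjusted p was 6.00e-07, lost in fry (adjusted p = 0.145) and without control replicate 1 (adjusted p = 0.0643). Of 23 cell-cycle genes 19 lay lower (median -0.33; camera adjusted p = 2.79e-04), among them Mcm3 (-0.59 ± 0.23), E2f1 (-0.67 ± 0.39), Mcm4 (-0.37 ± 0.23) and Pcna (-0.27 ± 0.15), 0 of which passed in limma. Of 18 mTEC markers 15 lay higher (median 0.21; camera adjusted p = 0.0497), among them Ccl19 (0.77 ± 0.47), Fezf2 (0.39 ± 0.27), Aire (0.40 ± 0.28) and Ccl21a (0.82 ± 0.66), with an adjusted p = 0.654 with an estimated correlation, and the list turned direction without control replicate 1 (adjusted p = 0.958). Of genes high in mTEC but outside that list, Pth was at 29.5 and 36.0 FPKM in cTEC Trap replicates 3 and 4 against 0 to 0.08 in the other 4 cTEC libraries, and Lyz2 at 3.21 and 7.63 against 0.35 to 1.95, both chosen after the values were seen. The log2 change of the cortical cytokine gene Il7 was -0.30 ± 0.26.

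The single gene called in cTEC was the X-linked homeobox gene Rhox5, which lies on chromosome X at 37804842 to 37808876, plus strand. It fell from 3.64 and 5.69 FPKM in controls to 0.08 to 0.15 FPKM in the 4 Trap libraries (-2.33 ± 0.15, SE; limma adjusted p = 4.04e-10). Rhox5 was at 0 FPKM in both mesenchymal populations and endothelium and at 0 to 0.40 FPKM in mTEC. Its SE and adjusted p therefore borrow from populations in which it is silent and do not measure the spread between cTEC libraries alone. With no change simulated, the same fit called a median of 1 gene in cTEC (0 to 7), which 1 call does not exceed. Without either cTEC control Rhox5 no longer reached 1 FPKM in 2 libraries and was not tested, and the fit on the 6 cTEC libraries gave an adjusted p of 0.0914. The count was 3 without control replicate 1 and 2 without Trap replicate 2 or 4. Rescaling to TPM gave 1 higher and 2 lower genes.

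In CD140a-positive mesenchyme, limma called 0 genes (609 at an unadjusted p under 0.05, smallest adjusted p = 0.0668), the fit on 6 libraries called 0 (669) and 1 weight per population called 1, Zkscan16, which was named after its values were seen (2.50 ± 1.31 to 0.463 ± 0.388 FPKM). As values, Phlda3, a p53 target that represses Akt, was at 1.44 ± 0.163 FPKM in controls and 5.41 ± 2.00 FPKM with Trap, and the laminin gene Lamc1, Itpripl2, Gpr173 and Ppp1r2 had log2 changes of 0.40 ± 0.11, 0.54 ± 0.14, 0.90 ± 0.25 and 0.46 ± 0.13 (SE). Stc1 (-1.01 ± 0.27), Tyw5 (-0.84 ± 0.23), Cep19 (-0.94 ± 0.26), Epyc (-0.90 ± 0.25) and Naa10 (-1.44 ± 0.41) lay lower. The p53 target list passed in camera (adjusted p = 0.0118) with 9 of 14 genes above 0, a median of 0.06 and a mean of 0.30, Bax (1.13 ± 0.41), Cdkn1a (0.85 ± 0.37) and Eda2r (0.64 ± 0.33) next to Phlda3, 0 called over all genes and 1 adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.319 with an estimated correlation) and without control replicate 2 (adjusted p = 0.329) or Trap replicate 1 (0.0631) or 2 (0.0806). Leaving out control replicate 1 or 2 gave 2 or 9 calls, and leaving out Trap replicate 2 or 4 gave 2 or 1.

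**Figure D4:**
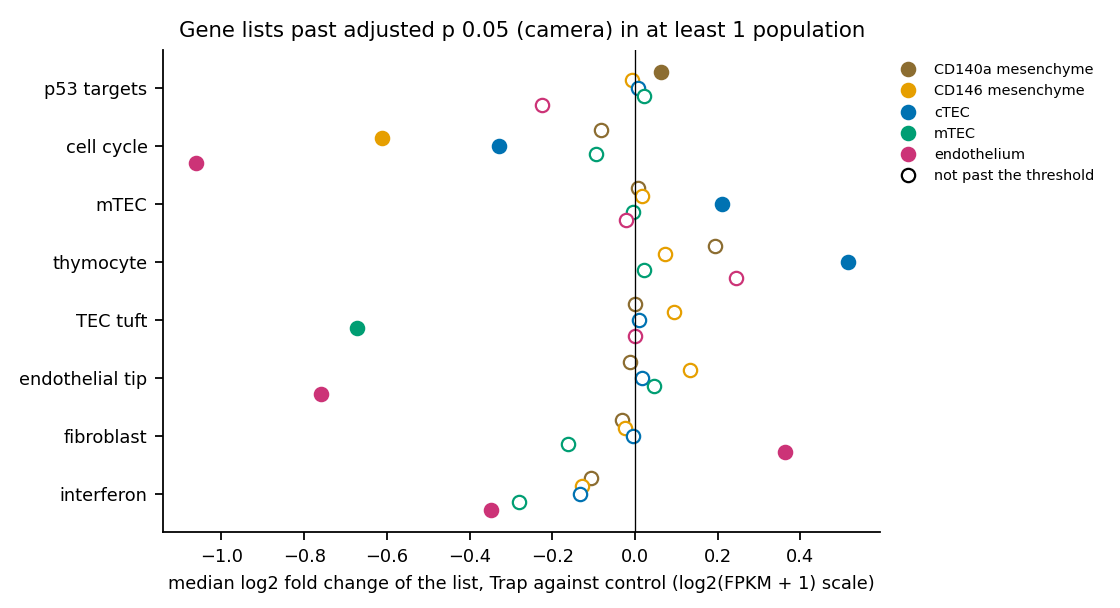
Median log2 fold change with Trap, on the log2(FPKM + 1) scale, of the 8 gene lists that passed camera at an adjusted p of 0.05 in at least 1 population, by population (colours; filled where the list passed). The cell-cycle list lies lowest in endothelium (-1.06) and CD146-positive mesenchyme (-0.61), and the thymocyte list highest in cTEC (0.51).

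VEGF ligands and receptors themselves did not pass in any population. Of the 10 tested genes, Vegfa was highest in CD140a-positive mesenchyme, at 49.7 ± 3.52 FPKM in controls (SD, n = 2) and 62.1 ± 4.05 FPKM with Trap (SD, n = 4), a log2 change of 0.32 ± 0.15 (SE). Its changes were -0.34 ± 0.15 in mTEC, -0.03 ± 0.15 in cTEC, 0.01 ± 0.15 in CD146-positive mesenchyme and -0.00 ± 0.15 in endothelium. In endothelium Kdr, the main signalling receptor for VEGF-A, was at 141 ± 13.7 and 100 ± 8.20 FPKM (-0.49 ± 0.21; limma adjusted p = 0.265), Flt1 changed by -0.17 ± 0.22, Flt4 by -0.23 ± 0.29, Nrp1 by -0.24 ± 0.19, Nrp2 by 0.12 ± 0.25, Vegfb by 0.30 ± 0.56, Vegfc by -0.50 ± 0.36 and Figf by 0.26 ± 0.53. Pgf, the placental growth factor gene, had a log2 change of 1.09 ± 0.33 in endothelium, from 1.85 to 5.16 FPKM on average (limma adjusted p = 0.0898). In CD140a-positive mesenchyme it stood at 2.34 ± 0.184 and 6.01 ± 1.23 FPKM, where Figf had a log2 change of -0.61 ± 0.53. The Notch ligand gene Dll4 was at 28.1 ± 4.00 and 15.9 ± 5.59 FPKM in endothelium (-0.84 ± 0.32; limma adjusted p = 0.201). The epithelial growth factor genes Fgf10 and Fgf7 were at 63.4 ± 2.13 and 41.1 ± 3.31 FPKM and at 39.2 ± 6.65 and 25.1 ± 5.53 FPKM in CD140a-positive mesenchyme, without passing. Sorting markers did not pass either, with log2 changes of 0.11 ± 0.23 for Pecam1, 0.07 ± 0.46 for Epcam, -0.07 ± 0.32 for Enpep, -0.21 ± 0.30 for Mcam and 0.21 ± 0.23 for Ptprc in endothelium, 0.14 ± 0.30 for Mcam in CD146-positive mesenchyme, -0.23 ± 0.46 for Epcam in mTEC and -0.03 ± 0.23 for Pdgfra in CD140a-positive mesenchyme.

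The calls of different populations shared 1 gene. Mcm3 was lower in both CD146-positive mesenchyme and endothelium, where 0.0284 shared genes are given by independent lists of 2 and 233 genes (Fisher's exact test, p = 0.0282, adjusted p = 0.563 over 20 pairs and directions). The other pairs shared 0 genes. Fold changes of all tested genes correlated across genes with r = 0.0495 to 0.124 between populations, and genes are not independent replicates. No control library was shared between populations, but whether libraries with the same number share animals is not stated. Differences between Trap libraries alone (2 against 2), with the same numbers in both populations, added after these values were seen, correlated at -0.0202 to 0.0885, with a median of 0.0238 against 0.0823 for Trap against control.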

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

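Of 286 groups of 4 Trap libraries examined (lists, library measures and named genes), 16 held a library far from the other 3, and chance flags about 1 in 20 such groups. In endothelium, Trap replicate 2 stood apart for Esm1 (38.5 FPKM against 0.67 to 2.71), Col6a3 (4.09 against 2.19 to 2.26), Vegfc (26.8 against 13.5 to 15.3) and Flt4 (29.2 against 14.8 to 16.4). Trap replicate 4 stood apart there for Mcm4 (3.12 against 5.37 to 5.74) and Hist1h2bj (0.59 against 0 in the others). Hbb-bs in CD146-positive mesenchyme was at 0.21 FPKM in Trap replicate 2 and 0 in the others, and Odam in mTEC at 1.16 FPKM in Trap replicate 1 against 2.16 to 2.22. Among mean log2 levels of lists, the libraries apart were CD140a Trap replicate 4 for lymphatic genes (1.61), CD146 Trap replicate 3 for mTEC genes (0.866), cTEC Trap replicate 2 for lymphatic genes (1.23), cTEC Trap replicate 4 for tuft genes (0.65) and cTEC Trap replicate 3 for pan-epithelial genes (4.19). The others were mTEC Trap replicate 1 for pericyte genes (2.00), and in endothelium Trap replicate 3 for Notch genes (3.45) and Trap replicate 4 for erythroid genes (3.36).

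A difference between groups drew attention to 46 genes and 4 lists that passed for a Trap change in endothelium unlike the mean of the other populations. Simulations with no change gave a median of 98 genes (52 to 147) by the same fit, so the 46 do not exceed that number. The named genes were Muc1 (2.24), Foxp4 (1.51), Mthfsl (1.39), Rab11fip5 (1.38), Nfil3 (0.95), Plcb4 (0.93), Il6st (0.71), Hist1h2bj (-3.18), Cdc42ep5 (-2.56), Gins1 (-2.47), Ccnd1 (-2.28), Olfr1394 (-2.20), Lalba (-2.13), Rrm2 (-1.94) and Catip (-1.91). The lists were tip cell (-0.78), basement membrane (-0.30), fibroblast (0.40) and cell cycle (-0.93). In camera with an estimated correlation, the tip cell list alone still passed (adjusted p = 0.00202).

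The fall of cell-cycle transcripts in endothelium was weighed first, with the test on level-matched lists fixed before its result and the other 2 tests chosen after the result was seen. Lower complexity acting alike on genes of the same level is not borne out. The list's median lay at percentile 0 of 10000 level-matched lists (-0.61 to 0.25). Those lists held genes drawn at random, so a part for library quality stays open. The list mean was 1.63 and 1.59 in Trap replicates 2 and 4 (10298 and 10572 genes at 1 FPKM) and 2.14 and 2.09 in 1 and 3 (11011 and 11228). In controls (11163 and 11304 genes) it was 3.13 and 3.07. Nor are fewer carried-over thymocytes borne out, since thymocyte genes had a median of 0.117 FPKM in control endothelium. Their list mean was 0.475 and 0.483 in controls and 0.512 to 0.728 with Trap, though Lck fell from 6.40 and 5.37 to 0.19 to 3.29 FPKM. A fall of like size in all 5 populations is not borne out, since the largest difference between a control and a Trap library in the list mean was 0.31 in mTEC, 0.52 in cTEC and 0.70 in CD140a-positive mesenchyme, below the smallest in endothelium (0.93), while those in CD146-positive mesenchyme, 0.00220 to 1.14, overlap it and leave a fall like that of endothelium open there (this test replaced the adjusted p = 0.0670 of the list difference with an estimated correlation, which had left the question open). A smaller fall shared by all 5 stays open, since the list mean was lower with Trap in each, from 3.68 to 3.56 in mTEC and from 2.80 to 2.75 in CD140a-positive mesenchyme. An action of Trap on endothelium, direct or through other cells, was not tested and stays open, and among the 15 ways to take 2 of 6 endothelial libraries as controls the real one had the largest difference in list mean, -1.24 against at most 0.997 in size (exact p = 0.0667, the smallest possible).

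For the thymocyte transcripts higher in cTEC with Trap, the test of a second list was fixed before its result and the test without control replicate 1, and later the spread it is held to, were chosen after the result was seen. More carried-over thymocytes, or thymocyte RNA, in the Trap cTEC libraries could account for it. A second list of thymocyte genes had a median at percentile 99.97 of 10000 level-matched lists (0.21 over 15 genes, 11 of them above 0). No member passed in limma, and 7 of the 15 reached 1 FPKM in mesenchyme or endothelium, so the list is not confined to thymocytes. The matched lists held genes drawn at random, and the second list was read in the same libraries, control replicate 1 included. Its percentile therefore does not separate carry-over from a low control replicate 1 or from transcripts made in cTEC. A low level in cTEC control replicate 1 alone stays open: without that library the median change was 0.34, with a spread of 0.27, against 0.51 with all libraries, the list no longer passed (adjusted p = 0.0643), and the list mean was 2.78 in the other control against 2.79 to 3.32 with Trap. The design does not separate more thymocytes bound to cTEC from transcripts made in cTEC.

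For the mTEC genes that passed with Trap, both tests were chosen after the result was seen. A spread borrowed from populations in which the genes are silent could account for the number, since the same fit called a median of 111 genes with no change simulated, a median of 86 of them silent in the other 4 populations, as were 52 of the 53 lower genes. A loss from the tissue-restricted repertoire stays open, since that list's adjusted p was 0.685 with an estimated correlation.

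Samples were also regrouped, a test fixed before its result. For each population contrast 1 of 100 groupings, the real one, called as many genes as the real one. Libraries correlated at 0.881 to 0.980 within the sorted populations and 0.603 to 0.868 between them, so a mixed grouping could hardly match the real one. The outcome shows only that the populations differ and does not bear on the size of the counts. The real and highest other counts were 8227 and 2476 for CD140a-positive mesenchyme, 7089 and 1740 for CD146-positive mesenchyme, 7517 and 2611 for cTEC, 9172 and 466 for mTEC, 8561 and 32 for endothelium, 6768 and 4255 for cTEC against mTEC, and 5120 and 2937 for the mesenchymal populations. For Trap against control 15 splits exist in each population, too few for a share under 0.05. As many genes as the real split were called in 15 splits in CD140a-positive mesenchyme (0 real, 3 in the highest other), 4 in CD146-positive mesenchyme (3 and 209), 11 in cTEC (1 and 6), 9 in mTEC (57 and 233) and 3 in endothelium (286 and 536). The highest split counts, 209 in CD146-positive mesenchyme and 233 in mTEC, were several times the real ones. With no change simulated, the same fit called a median of 20 (13 to 30) and 111 (80 to 145). The split with 209 calls set CD146 control replicate 1 and Trap replicate 2 against the rest. The split with 233 set mTEC Trap replicates 1 and 2, which also stood apart in genes at 1 FPKM, against the rest. A structure of the samples thus goes with the mTEC split. What set these libraries apart was not tested, and the simulated genes varied independently.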

How the results depend on the processing

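Results for Trap depended on how the spread between libraries was estimated. Between populations, the balance of higher and lower genes turned with scaling, in mTEC from 6304 and 2868 to 4268 and 5753 and in cTEC against mTEC from 2116 and 4652 to 4003 and 3080 (quantile normalization), in CD146-positive mesenchyme from 2984 and 4105 to 3858 and 3458 (TPM) and between the mesenchymal populations from 2220 and 2900 to 2525 and 2458 (upper quartile scaling). Where a cause is not stated, the cause was not tested. The number of genes past the threshold was 2 in cTEC and 9 in mTEC with a pseudocount of 0.1. With no filter it was 4 in CD140a-positive mesenchyme, 13 in CD146-positive mesenchyme and 199 in mTEC, and with a filter at 5 FPKM, which tests fewer genes, 1 in CD146-positive mesenchyme, 0 in cTEC, 6 in mTEC and 27 for the difference between endothelium and the others. TPM gave 7 in CD146-positive mesenchyme and 3 in cTEC, and quantile normalization 176 in endothelium and 28 for the difference. Library weights gave 1, 6, 5 and 24 in CD140a-positive and CD146-positive mesenchyme, cTEC and endothelium, and 12 for the difference. With only the 6 libraries of a population the count was 0 in CD146-positive mesenchyme, cTEC, mTEC and endothelium. With control libraries only, fewer samples, it was 4808, 3689, 4050, 5509 and 5294 for CD140a-positive and CD146-positive mesenchyme, cTEC, mTEC and endothelium, 3352 for cTEC against mTEC and 2162 for the mesenchymal populations. Of alternatives chosen after the data were seen, genes expressed in the population gave 1 in CD140a-positive mesenchyme, and 1 weight per population gave 1, 6, 8 and 13 in CD140a-positive and CD146-positive mesenchyme, cTEC and endothelium and 5 for the difference. Without mTEC Trap replicates 1 and 2 the count in mTEC was 138, 72 higher and 66 lower, against 4 and 53, and the interferon list in endothelium (adjusted p = 0.0692) and the mTEC list in cTEC (adjusted p = 0.0886) lost their calls. Of 10 lists, 0 passed with an estimated correlation, 2 in fry and 0 in fry on the 6 libraries. Of the same 10, 8 passed after upper quartile scaling, 9 after quantile normalization and 7 with a pseudocount of 0.1.

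With the replicate number as a block, the count was 0 in CD146-positive mesenchyme, 2 in cTEC and 18 in endothelium, of which 11 were shared with the 286. In mTEC it was 55, of which 23 were shared with the 57. Of the 10 lists that passed in camera, 7 kept their call under this block, where 12 lists passed, and the tip list in endothelium had an adjusted p of 0.0618. Under this block 3 small values turned, to 0.0174 for Flt4 in endothelium, -0.0583 for Vegfa in CD146-positive mesenchyme and 0.0133 for Pdgfra in CD140a-positive mesenchyme. Residuals of libraries with the same number in different populations correlated at -0.0242 to 0.102 in Trap, 1 of 40 pairs above 0.1, which is below the bar set for pairing, so the main test did not use it. The same number was the best match of 4 in 22 of the 40, and the median was 0.0225 against -0.00855 for other numbers, a hint of shared pools from the data, not the design.

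With 1 library left out, the remaining control being assumed to vary like the other groups, counts ranged from 0 to 9 in CD140a-positive mesenchyme, 2 to 19 in CD146-positive mesenchyme, 1 to 3 in cTEC, 30 to 149 in mTEC, 89 to 468 in endothelium and 31 to 223 for the difference. For the populations they ranged from 6774 to 8563 (CD140a), 5589 to 7387 (CD146), 6008 to 7818 (cTEC), 7605 to 9487 (mTEC), 7366 to 8658 (endothelium), 5581 to 7115 (cTEC against mTEC) and 4179 to 5448 (mesenchymal populations), and for lists from 7 to 13.

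Values that turned were near 0 or of genes at low levels. Vegfa in endothelium was 0.0588, 0.0465 and 0.0547 with upper quartile scaling, TPM and quantile normalization and 0.00929 with the Y-linked level as covariate. Epcam there was -0.42 with a pseudocount of 0.1, -0.21 in TPM and -0.15 with library weights, and Enpep 0.00489 after quantile normalization and 0.0178 with library weights. Krt19 in cTEC was 0.95 with a pseudocount of 0.1 and 0.56 in TPM. With 1 library left out, values that turned ranged from -0.0957 to 0.0824 for Vegfa, -0.11 to 0.76 for Vegfb, -0.40 to 0.48 for Epcam and -0.32 to 0.18 for Enpep in endothelium, and from -0.0533 to 0.0779 for Vegfa and -0.0682 to 0.35 for Mcam in CD146-positive mesenchyme. Further ranges were -0.24 to 0.17 for Vegfa in cTEC, -0.0928 to 0.0401 for Pdgfra in CD140a-positive mesenchyme and -0.51 to 0.18 for Krt19 in cTEC, and 8.02e-05 to 0.958 for the adjusted p of the mTEC list in cTEC, the last without control replicate 1.

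Of 207 values of named genes, those that kept direction and side of the threshold numbered 202 with no filter, 200 with upper quartile scaling, 188 with quantile normalization, 179 in TPM, 173 with a pseudocount of 0.1, 159 with the replicate block, 158 with library weights and 157 with 1 weight per population. Most others kept direction and lost the call (49 with 1 weight per population, 46 with library weights). Of 118 values tested with only the 6 libraries, 67 kept and 51 lost the call. The depth behind the FPKM values is unknown, so what depth limits cannot be stated.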

Other observations

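Programs beyond the sorting markers also separated the populations. Interferon-response genes were higher in cTEC for 15 of 16 (median log2 difference 2.04) and lower in CD140a-positive mesenchyme for 16 of 16 (-1.99). In mTEC 10 of 10 MHC class II genes (4.19), 15 of 17 cholesterol synthesis genes (1.35) and 19 of 23 cell-cycle genes (0.67) were higher, and 14 of 14 basement membrane genes were lower (-2.34), while 12 of 14 basement membrane genes were higher in endothelium (1.25). Myeloid genes were higher in mTEC for 9 of 10 (1.56), which stands beside these groups.

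Vegfa was highest in CD140a-positive mesenchyme (58.0 ± 7.31 FPKM, SD, n = 6), and its receptors Kdr and Flt1 in endothelium. Kitl, the ligand of Kit, and Cxcl12 averaged 106 and 85.2 FPKM in endothelium, and Cxcl12 59.3 FPKM in cTEC. Igf1 and Fgf10 averaged 121 and 48.5 FPKM in CD140a-positive mesenchyme, and the Wnt ligand gene Wnt4 29.9 FPKM in cTEC.

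The lists that passed for Trap in no population had these smallest camera adjusted p-values and median log2 changes: VEGF ligands and receptors 0.0895 (CD140a-positive mesenchyme, 0.18), pan-endothelial 0.835 (endothelium, -0.06), arterial 0.819 (cTEC, -0.10), venous 0.0895 (endothelium, 0.42), capillary 0.104 (CD146-positive mesenchyme, 0.33), lymphatic 0.403 (endothelium, 0.43), Notch 0.319 (endothelium, -0.39) and basement membrane 0.159 (CD140a-positive mesenchyme, 0.06). For cTEC markers it was 0.709 (CD146-positive mesenchyme, 0.12), tissue-restricted antigens 0.159 (mTEC, -0.66), pan-epithelial 0.272 (endothelium, 0.11), thymopoietic factors 0.851 (CD146-positive mesenchyme, -0.14), MHC class II 0.583 (cTEC, 0.11), pericyte and smooth muscle 0.458 (endothelium, -0.26), hypoxia 0.0895 (CD140a-positive mesenchyme, 0.16), immediate early stress 0.146 (CD146-positive mesenchyme, -0.20) and cholesterol synthesis 0.620 (CD146-positive mesenchyme, -0.10). For erythroid genes it was 0.153 (CD146-positive mesenchyme, -0.38), myeloid 0.596 (cTEC, -0.04), neural and glial 0.0895 (cTEC, 0.18), mesothelial and parathyroid 0.148 (cTEC, 0.10) and Y-linked 0.467 (mTEC, 0.51).

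Y-linked genes followed the replicate number across populations, a test chosen after the result was seen. Their mean log2 level averaged 2.70 and 3.52 in control replicates 1 and 2, and 4.00, 3.56, 3.92 and 1.87 in Trap replicates 1 to 4, over the 5 populations. Libraries with the same number could come from the same pools of animals of mixed sex, since shuffling the numbers within each group gave a permutation p of 2.0e-05.

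Pth ranged from 436 to 2463 FPKM over the 6 mTEC libraries, and this test too was chosen after the result was seen. Parathyroid cells carried over into the sort could account for it, as could expression by mTEC. The parathyroid genes Gcm2 (1.70 to 7.14 FPKM) and Casr (9.15 to 13.4 FPKM) were present in each library and followed Pth across the 6 libraries (Spearman rho 0.886 and 0.943). That order goes with carry-over, but Casr varied far less than Pth, and Gcm2 stayed below 5 FPKM in some libraries, short of the level set for it. Carry-over and expression by mTEC both stay open.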
